A study of Caenorhabditis elegans with 5 samples.

How the data were processed

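The data were 5 two-colour Agilent arrays of Caenorhabditis elegans fem-1(hc17) oocyte RNA, each with a day 8 sample against a day 3 sample. How the oocytes were collected is not given in the sources used here. RNA was extracted with a Qiagen RNeasy kit, per the labels' protocols. Which age was in which dye was taken from the labels, and every ratio was turned so that day 8 is over day 3. The labels give 3 arrays with day 8 in Cy5 and 2 with day 3 in Cy5. The design text counts 3 of the arrays as dye-flipped without saying which, and which orientation it counts from is not given in the sources used here; the direction of every ratio and the dye term rest on the labels. The build of the probe coordinates is not given in the sources used here, so no coordinates are reported.

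The scanner files hold spot brightness as intensity on a linear scale, deposited as Agilent Feature Extraction 9.5.3.1 wrote it: mean signals and local background per dye, and processed signals after removal of a background surface and linear dye normalization, per the file headers. They also hold a log10 ratio of red over green made by the same software, per the file headers. The series table deposited by the authors holds log2 ratios with no stated scale, centring or direction. Set against the scanner's log ratio, its values were the same ratio on the log2 scale, day 3 over day 8, on 100% of spots within 0.002; column medians were 0, 0, 0.047, 0 and 0 for arrays 3, 5, 6, 7 and 8, so that no further centring was applied. Slide and scan were taken from the labels as 2 batches, with array 3 alone in the first and the other 4 in the second.

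Mean signals were corrected with normexp (offset 50) and normalized within each array by loess (span 0.3), with control spots and spots with outlier flags at weight 0 and then left out; saturated spots were kept. There were 42964 spots other than controls and 20401 probes, most of them with 2 spots. Probe names were matched to gene symbols through a table of the WBcel235 assembly: 19057 probes had a symbol and 1344 kept the name in the files. Spots were averaged per probe, and detected probes per gene. A probe was kept when it was well above background at either age on at least 3 of 5 arrays, which left 15959 probes; of 689 genes with several kept probes, 151 had probes in both directions. Gene ratios were fitted with lmFit and eBayes in limma 3.58.1 (R 4.3.3, with the packages statmod, version 1.5.0, and data.table, version 1.17.8), with a dye term and an age term, which left 3 residual degrees of freedom, and a two-sided Benjamini-Hochberg adjusted p under 0.05. The dye term was used because the orientations were not balanced.

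Gene lists and gene classes with at least 10 measured members were tested with camera in limma, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the 34 lists or the 150 classes. Camera compares a list with the remaining genes; fry tests whether its genes move in 1 direction on balance, and its mixed form whether they change in either direction. The lists were kinetochore and checkpoint, spindle and centrosome, cohesin and condensin, DNA repair, DNA replication, cell cycle, maternal RNA, eggshell and yolk uptake, small RNA, respiratory chain, mitochondrial dynamics, proteasome, heat shock, ribosomal proteins, nucleolus, DAF-16 targets, TGF-beta and insulin, apoptosis, autophagy and lysosome, histones, chromatin modifiers, early zygotic genes, innate immunity, ubiquitin-like modification, nuclear pore, RNA splicing, lipid and vitellogenesis, and markers of intestine, muscle and pharynx, hypodermis and cuticle, neurons, gonadal sheath, coelomocytes and sperm. Of the 47 intestine markers, 33 are also in another list.

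The fit, the lists, the rule for naming genes and the first set of other settings were chosen before the data were examined. The rule names genes past the threshold, up to 4 members of each list with the smallest adjusted p, the 3 brightest of each list of other cells, and fem-1. No gene passed the threshold, equal adjusted p were ordered by p, and the rule then named 141 genes, none of them below background or saturated at an age on every array. Saturation on fewer arrays did occur among them: cey-2 and col-63 were each saturated on 3 arrays at day 8 and on 1 at day 3. The text gives a part of these, mostly the members of each list with the smallest p, and this narrowing was made after the values were seen. asp-14, eif-3.I, osm-11, msp-113, rol-1 and dpy-13 lie outside the rule and were chosen after their values were seen.

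The settings chosen then were no dye term, 2 other background corrections, median centring, the scanner's log ratio, Aquantile between arrays, the deposited series values, a looser and a stricter filter on dim probes, outlier spots kept, the brightest probe of a gene, arrays 6 and 7 counted as 1 replicate, collection day and slide as random blocks, array weights, a trended and robust eBayes, 2 other thresholds, a plain test, the estimated correlation, fry, and each array left out. Scaling between arrays, leaving out arrays 6 and 7, leaving out array 3 with no dye term, turning the sign of array 3, and leaving out saturated genes were added after the data were seen, as were the limits that set which differences between settings are described as a change.

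The procedure was tested on simulated data with the spread of these arrays, 15179 genes and 200 of them changed. It called 5 of 67 genes changed 1.5-fold, 26 of 67 changed 2-fold and 52 of 66 changed 4-fold, none with the wrong sign, and 2 of 14945 unchanged genes. A simulated shift of 1 list was found, and 0 of the other lists passed. Simulated genes varied independently, while the estimated correlation within lists of the real data reached 0.52 for maternal RNA regulators. The simulation therefore cannot tell how often correlated genes give a false list call.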

Results

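Oocytes of the nematode Caenorhabditis elegans were compared at 2 adult ages, day 3 and day 8. The animals carried fem-1(hc17), a mutation that feminises the germline so that hermaphrodites make oocytes and no sperm of their own. Total RNA of a day 8 oocyte sample and of a day 3 oocyte sample was hybridised directly against each other on each of 5 two-colour microarrays, named here by the replicate numbers of the labels (arrays 3, 5, 6, 7 and 8). Day 8 was in Cy5 on arrays 3, 7 and 8 and in Cy3 on arrays 5 and 6. The comparison addresses how the oocyte transcriptome differs between younger and older animals. The samples of arrays 6 and 7 were collected on the same days at both ages, and array 3 lay alone on its slide and scan. The labels name separate collections but not separate cultures, so that p-values measure only the spread between these samples.

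Between 64.8% and 80.7% of the probes were well above background at day 8, and at most 83.8% at day 3, on array 6. The median Cy3 signal was lowest on array 5, at 50.5 over a background of 23, and the median Cy5 signal was highest on array 6, at 196. The number of arrays, 5, limits the precision: the median standard error of a gene was 0.11 and the median SD between arrays was 0.26 (log2).

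The day 8 over day 3 log2 ratios of arrays 6 and 7 correlated most closely across genes (Pearson r = 0.897, Spearman rho = 0.848). Genes are not independent replicates, and this coefficient only describes those arrays. The other correlations among arrays 5, 6, 7 and 8 lay between 0.224 and 0.609. Array 3 correlated with none of them beyond 0.0601, and its coefficient with array 8 was -0.130. The SD of the log2 ratios was 0.40, 0.19, 0.96, 0.64 and 0.33 on arrays 3, 5, 6, 7 and 8, so that array 6 carried the widest ratios and array 5 the narrowest.

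**Figure D1:**
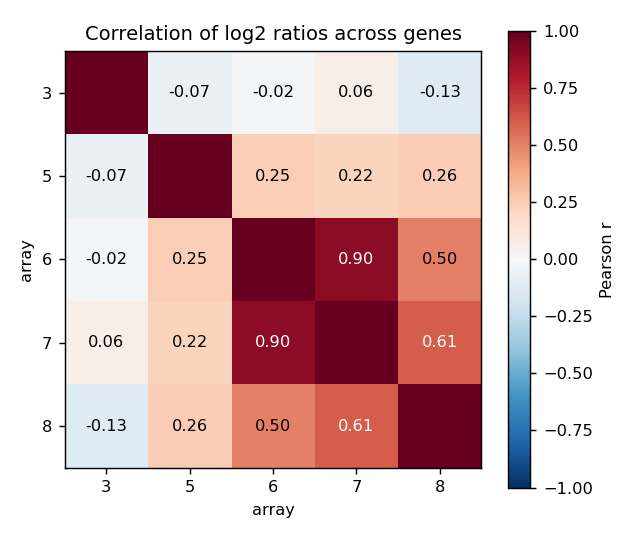
Pearson correlation across genes of the day 8 over day 3 log2 ratios of each pair of arrays; rows and columns are arrays, colour and printed number give r. Arrays 6 and 7 reach 0.90, and array 3 lies between -0.13 and 0.06 with the others.

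Of single genes at day 8 against day 3, cpr-1, a cathepsin B-like cysteine protease, had a log2 ratio of -0.86 ± 0.07 (SE, n = 5 arrays), spp-1, an antimicrobial saposin-like protein, -1.13 ± 0.12, and vit-2, a yolk protein precursor, -0.95 ± 0.11. asp-14, an aspartyl protease, stood at -0.83 ± 0.07, with array values from -1.29 to -0.48 and an SD of 0.38 over the arrays. In the other direction, eif-3.I, a subunit of a translation initiation factor, was at 0.73 ± 0.08 and osm-11, a secreted signalling protein, at 1.27 ± 0.20. Each of these 6 genes had the same direction on 5 of 5 arrays; asp-14, eif-3.I and osm-11 were chosen after their values were seen. None of them passed the test, each with a limma adjusted p of 0.374. cpr-1, spp-1 and vit-2 are also in the list of intestine markers, so that their values cannot be told apart from a different share of gut RNA in the samples.

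No gene passed: 0 of 15168 genes had a limma adjusted p under 0.05, 0 higher and 0 lower at day 8. At an unadjusted p under 0.05 there were 1129 genes, 335 higher and 794 lower, where 758 would be expected by chance for independent arrays. Of the 10 splits of the arrays into groups of 3 and 2, a comparison chosen after the data were seen, 3 had at least as many such genes, the real split included. The highest of the other splits had 1236, so that 1129 against 758 cannot be read as an excess due to age. With arrays 6 and 7, of shared collection days, averaged as 1 replicate, the count of the real comparison was 211. A plain one-sample test without moderation called 0 genes as well, with 1188 at an unadjusted p under 0.05. Of 15063 genes with a value on every array, 3165 had the same direction on all 5, of which 1423 were higher and 1742 lower; independent arrays would give 6.25%. With arrays 6 and 7 averaged, 3489 of these genes (23.2%) had the same direction in all 4 collections, where independent collections would give 12.5%. In simulated data, 38.8% of genes changed 2-fold and 78.8% of genes changed 4-fold were called. The simulated arrays were independent and equal in spread, which the real ones were not, so that these rates need not hold here. The count at an unadjusted p moved with single arrays other than array 3. It was 1125 without array 3, 5973 without array 5, 269 without array 6, 222 without array 7 and 367 without array 8, with 0 genes called in each case.

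Of 34 gene lists fixed before the data were examined, 12 differed from the remaining genes by camera with a preset correlation, 6 higher and 6 lower at day 8. With an estimated correlation, and by the rotation test fry for change in 1 direction, 0 of the 34 passed; by fry for change in either direction, the intestine and lipid lists passed. The split moved with the scaling: the scanner's own log ratio and the deposited series values each gave 18 lists higher and 4 lower, and scaling between arrays gave 5 higher and 3 lower. Within slide 2 and scan 2, which leaves out array 3, 13 lists and 0 genes passed, and with slide as a random block 12 lists and 0 genes; the medians of the 12 lists had the same sign in both. The median, mean and test of a list differed in sign for cell cycle genes (test higher), cuticle markers (mean -0.05), coelomocyte markers (mean -0.09), DAF-16 targets (mean -0.11, test lower) and ubiquitin-like modification (mean -0.01, test lower). An exact sign-flip test over the 5 array medians of a list cannot go below a two-sided p of 0.0625.

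**Figure D2:**
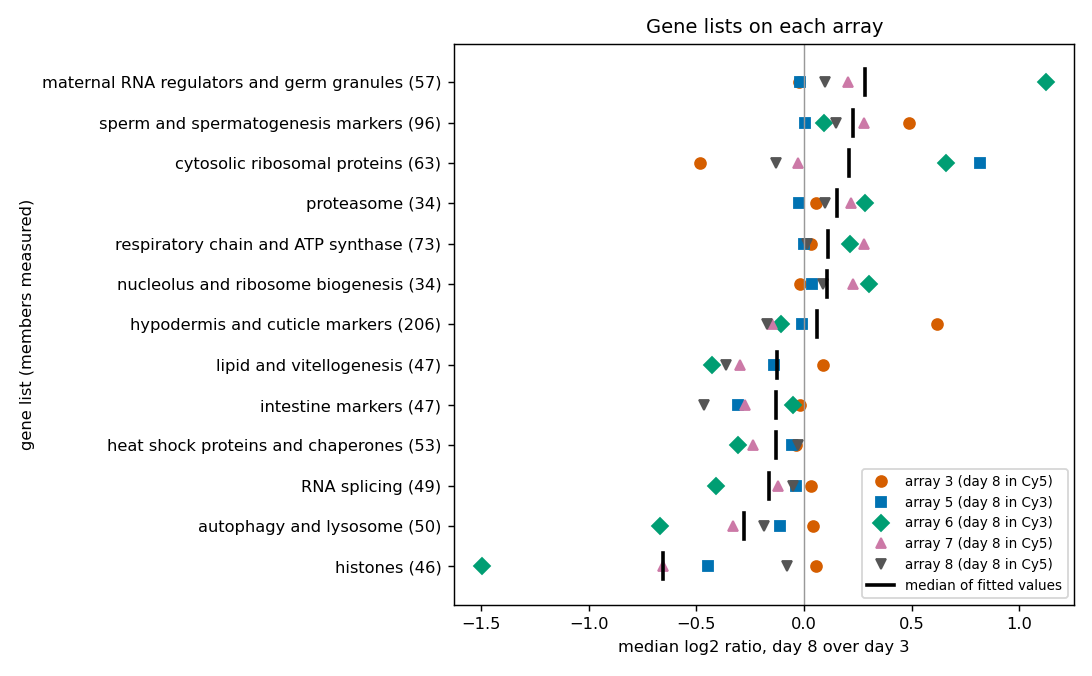
Median day 8 over day 3 log2 ratio of the 12 gene lists past the preset camera test and of the cuticle list, on each array (symbols) and over the fitted gene values (black bars); numbers of measured members stand in parentheses. The intestine list lies below 0 on all 5 arrays and the ribosomal list above 0 only on arrays 5 and 6, those with day 8 in Cy3. The direction of RNA splicing and heat shock proteins turns with the scanner's log ratio and the deposited series values, that of the proteasome with scaling between arrays, and that of the cuticle list with every scaling alternative but scaling between arrays.

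Genes of the intestine were lower at day 8 as a group. The list of 47 measured intestine markers had a median log2 ratio of -0.13, with 32 members below 0 and 15 above, and its median was below 0 on 5 of 5 arrays (camera adjusted p = 0.000228; adjusted p = 0.610 with an estimated correlation). No member passed over all genes tested; adjusted over the list alone, 11 members passed, all of them lower. By the fry test of change in either direction the list had an adjusted p of 0.00788. cpr-1 and spp-1 were its members with the smallest p. Of its 3 brightest members, asp-1 and asp-5, aspartyl proteases of the gut, were at -0.25 ± 0.29 and 0.12 ± 0.39, and far-2, a fatty acid and retinol binding protein, was at 0.17 ± 0.21. The camera call was lost without array 5 (adjusted p = 0.0894; 4.90e-15 to 0.0894 over the alternatives with the preset correlation), and the median was -0.23 without array 3, -0.26 without array 6 and -0.07 without array 8. Scaling moved the median to -0.61 between arrays, -0.37 with the scanner's log ratio, -0.30 with Agilent's processed signals and -0.24 with no background correction.

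Lipid and vitellogenesis genes, of which 12 of 47 are also in the intestine list, had a median of -0.13 (camera adjusted p = 0.00960; adjusted p = 0.610 with an estimated correlation). Adjusted over the list alone, 6 members passed, all of them lower. vit-2 was at -0.95 ± 0.11, and fat-2, a fatty acid desaturase, was 2.01-fold lower at day 8 (SE 0.12 on the log2 scale). vit-5 and vit-4, further yolk protein genes with near-identical copies that can share probe signal, were at -1.13 ± 0.19 and -1.14 ± 0.21. vit-2, fat-2, vit-5 and vit-4 are all among the genes shared with the intestine list. The list median was below 0 on 4 of 5 arrays, and the call was lost without array 5 (adjusted p = 0.0894, median -0.22), without array 8 (0.0681, median -0.05), with the scanner's log ratio and the deposited series values (0.0848 for each) and with scaling between arrays (0.128, the highest with the preset correlation, from 1.49e-05). Without array 3 the median was -0.31, and over the scaling alternatives it lay between -0.45 and -0.21. By the fry test of change in either direction the lipid list had an adjusted p of 0.0153.

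Innate immune effectors did not shift as a list: the 207 measured members had a median of -0.02 and a camera adjusted p of 0.250, with 0 passing adjusted over the list alone. The members with the smallest p were spp-1 and lys-2, a lysozyme at -0.95 ± 0.12; clec-63, a C-type lectin, was at -1.16 ± 0.18. The list passed as lower with no background correction (adjusted p = 0.0362, median -0.07), with Agilent's processed signals (0.0214, median -0.19) and with the scanner's log ratio (0.000499, median -0.38). Its adjusted p with the preset correlation reached 0.544 with scaling between arrays.

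**Figure D3:**
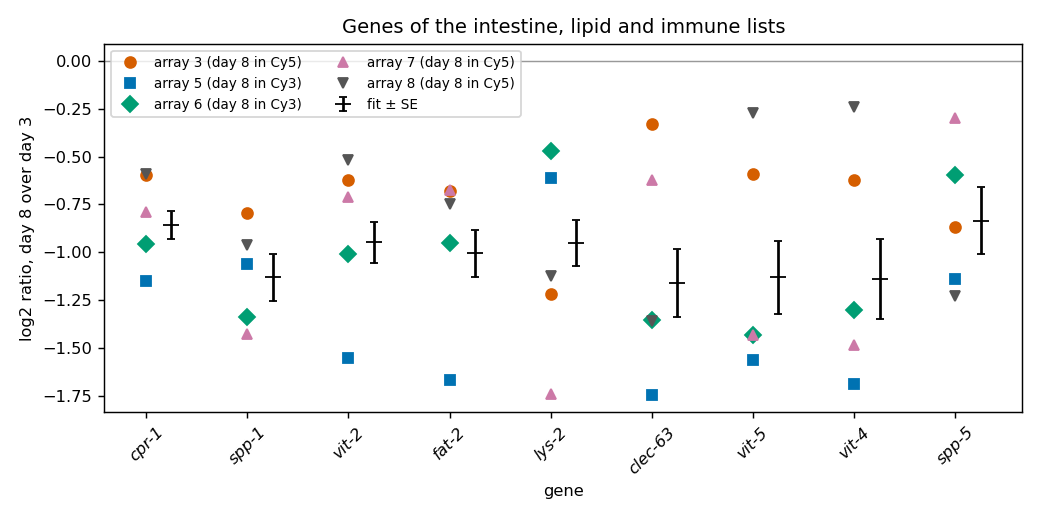
Day 8 over day 3 log2 ratio of the genes with the smallest p in the intestine, lipid and innate immune lists, on each array (symbols) and as the fitted value with its standard error (black). All 9 genes lie below 0 on all 5 arrays, with none past the adjusted test over all genes.

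Histone genes had the lowest median of all 34 lists in the fit as reported. With the scanner's log ratio innate immune effectors (-0.38), intestine markers (-0.37), early zygotic genes (-0.36) and cuticle markers (-0.34) were lower than histones (-0.30). Without arrays 6 and 7 intestine markers were lower, at -0.28 against -0.21. In the fit as reported, the 46 measured histone genes had a median log2 ratio of -0.66, a 1.58-fold lower level at day 8. Of these, 37 were below 0 and 9 above (camera adjusted p = 3.36e-06; adjusted p = 0.610 with an estimated correlation). The median was -1.49 on array 6 and 0.06 on array 3, and was below 0 on 4 of 5 arrays; without array 6 the list median was -0.34, with the scanner's log ratio -0.30 and with scaling between arrays -1.12. his-25 and his-64, which code for core histones, were at -0.86 ± 0.21 and -0.74 ± 0.21. Adjusted over the list alone, 0 members passed. Histone genes are near-identical copies, so that probes can share signal between members.

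Genes of autophagy and the lysosome had a median of -0.28 over 50 members, 38 of them below 0 (camera adjusted p = 0.000119; adjusted p = 0.610 with an estimated correlation). Adjusted over the list alone 1 member passed, cpr-1, which is also in the intestine list together with 4 further members. asp-4, an aspartyl protease of the lysosome, was at -1.46 ± 0.32, and atg-13, a component of the complex that starts autophagy, at -0.25 ± 0.07. The call was lost with the scanner's log ratio (adjusted p = 0.189, the highest with the preset correlation, from 1.99e-06), and the median was -0.08 there, -0.49 with scaling between arrays and -0.16 without array 6.

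Heat shock proteins and chaperones had a median of -0.13 over 53 members, below 0 on 5 of 5 arrays (camera adjusted p = 0.00401; adjusted p = 0.610 with an estimated correlation), but the median turned to 0.073 with the scanner's log ratio (adjusted p = 0.803, the highest with the preset correlation, from 0.00158) and was -0.08 without array 6. The heat shock call was also lost with Agilent's processed signals (adjusted p = 0.116, median -0.11) and with scaling between arrays (0.0604, median -0.26). Adjusted over the list alone, 0 members passed. pfd-1, a prefoldin subunit measured on 4 arrays, was at -0.73 ± 0.13, and hsp-4, the BiP chaperone of the endoplasmic reticulum, at -0.33 ± 0.07. F44E5.4, a cytosolic Hsp70 gene, had the lowest value of the 4 named members, at -2.94 ± 0.71. RNA splicing genes had a median of -0.16, with 42 of 49 members below 0 (camera adjusted p = 0.000228; adjusted p = 0.635 with an estimated correlation), and turned to 0.18 with the scanner's log ratio. lsm-6, a spliceosomal core protein, was at -0.32 ± 0.08 and ddx-15, a spliceosomal helicase, at -0.22 ± 0.07, with 0 members past the test adjusted over the list alone. The splicing call was lost without arrays 6 and 7 (adjusted p = 0.364, the highest with the preset correlation, from 1.97e-05), with a median of -0.03. It was also lost with Agilent's processed signals (0.0819, median -0.15), with median centring (0.106, median -0.18) and with scaling between arrays (0.107, median -0.15). With the scanner's log ratio the list passed as higher (adjusted p = 0.00757), and without array 6 its median was -0.07.

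Ribosomal protein genes were higher at day 8 as a group in the fit, unevenly over the arrays. The median of 63 members was 0.21, with 57 members above 0 (camera adjusted p = 8.63e-08; adjusted p = 0.610 with an estimated correlation). The array medians were 0.82 and 0.66 on arrays 5 and 6, where day 8 was in Cy3, and -0.48, -0.03 and -0.13 on arrays 3, 7 and 8, where it was in Cy5. In red over green terms, the median was below 0 on 5 of 5 arrays, and 51 members were saturated on at least 1 array. rpl-11.2, a large-subunit protein, was at -0.65 ± 0.16, against the direction of its list, and rps-5, a small-subunit protein, at 0.38 ± 0.10; adjusted over the list alone, 0 members passed. The call was lost without array 5 (adjusted p = 0.0894, the highest with the preset correlation, from 2.34e-28), where the median was 0.20. The list median was 1.83 with scaling between arrays, 0.65 with the scanner's log ratio, 0.40 with array 3 turned and 0.11 with no dye term.

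Genes of the nucleolus and ribosome biogenesis had a median of 0.11, with 27 of 34 members above 0 (camera adjusted p = 0.00272; adjusted p = 0.610 with an estimated correlation). nol-10 and grwd-1, both ribosome assembly factors, were at 0.36 ± 0.10 and 0.29 ± 0.10. Proteasome genes had a median of 0.15, also with 27 of 34 members above 0 (camera adjusted p = 0.000152; adjusted p = 0.610 with an estimated correlation), and turned to -0.01 with scaling between arrays, which ended the call (adjusted p = 0.0880, the highest with the preset correlation, from 3.39e-07). pas-7 and pbs-1, subunits of the core particle, were at 0.68 ± 0.16 and 0.23 ± 0.06. Genes of the mitochondrial respiratory chain and ATP synthase had a median of 0.11, with 57 of 73 members above 0 (camera adjusted p = 0.000880; adjusted p = 0.610 with an estimated correlation) and a median above 0 on 5 of 5 arrays. sdhd-1, a subunit of succinate dehydrogenase, was at 0.38 ± 0.10 and aco-2, mitochondrial aconitase, at 0.94 ± 0.24. Adjusted over the list alone, 0 members of these 3 lists passed. Without array 6 the medians of the 3 lists were 0.07, 0.08 and 0.05; without array 5 those of the proteasome and the respiratory chain were 0.24 and 0.18, and without array 7 that of the respiratory chain was 0.07. With the scanner's log ratio the medians of the nucleolus, proteasome and respiratory chain lists were 0.48, 0.51 and 0.47; with scaling between arrays that of the respiratory chain was 0.05, and with Agilent's processed signals that of the nucleolus was 0.18.

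Maternal RNA regulators and germ granule genes had a median of 0.28, with 51 of 57 members above 0 (camera adjusted p = 8.12e-07; adjusted p = 0.656 with an estimated correlation). glh-1, a germ granule helicase, was at 0.47 ± 0.13 and fog-1, a regulator of germ cell fate, at 0.97 ± 0.33. Adjusted over the list alone, 0 members passed. In Cy5, 6 of the 57 members were saturated on at least 1 array, which limits the ratios of bright members. The median was 1.12 on array 6 and between -0.02 and 0.21 on the other arrays. It was 0.03 without array 6, 0.55 without array 5, 0.17 with arrays 6 and 7 averaged, 0.06 with scaling between arrays and 0.59 with the scanner's log ratio. Without arrays 6 and 7 it was 0.01 and the call was lost (adjusted p = 0.0906, the highest with the preset correlation, from 5.99e-11).

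None of the lists of chromosome segregation and the cell cycle passed the preset camera test. Kinetochore, spindle checkpoint and anaphase-promoting complex genes (40 members) had a median of -0.06 and a camera adjusted p of 0.208, with kbp-2 and hcp-2, both of the kinetochore, at -0.33 ± 0.08 and -0.30 ± 0.08. Spindle, centrosome and chromosomal passenger genes (45 members) had a median of -0.13 and an adjusted p of 0.119, with gpr-1, a regulator of spindle positioning, at -0.24 ± 0.07 and ran-3, the exchange factor of the Ran GTPase, at 0.21 ± 0.06. The medians of both lists were below 0 on 5 of 5 arrays and turned to 0.30 and 0.20 with the scanner's log ratio. Cohesin, condensin and synapsis genes (43 members) had a median of 0.05 that turned to -0.26 with scaling between arrays, and an adjusted p of 0.847, with top-2, a topoisomerase, at -0.45 ± 0.12 and scc-1, a cohesin subunit, at -0.22 ± 0.06. Cell cycle kinases, cyclins and regulators (49 members) had a median of -0.02 and an adjusted p of 0.885, with gsp-3, a phosphatase of sperm, at 0.51 ± 0.15 and cya-1, a cyclin, at -0.35 ± 0.11; its median turned to 0.34 with the scanner's log ratio. In each of these 4 lists, 0 members passed adjusted over the list alone. All 4 passed with the scanner's log ratio, higher at day 8, with adjusted p from 7.10e-05 for cohesin to 0.00279 for cell cycle genes. The cohesin median was -0.06 without array 6 and 0.18 without array 5, and the cell cycle median turned to 0.00 without array 7 and to 0.01 without array 8. Without array 6 the kinetochore and spindle lists passed, lower at day 8 (adjusted p = 0.00460 and 0.0256), and over the alternatives with the preset correlation their adjusted p reached 0.844 and 0.687.

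DNA damage response and repair genes (63 members) had a median of 0.11 that turned to -0.18 with scaling between arrays, and a camera adjusted p of 0.108; polh-1, a translesion polymerase, was at 0.42 ± 0.10 and rev-1, of the same pathway, at -0.41 ± 0.12. DNA replication genes (48 members) had a median of 0.06 that turned to -0.03 with scaling between arrays, and an adjusted p of 0.208, with top-2 and crn-1, a nuclease at 0.28 ± 0.09, as the members with the smallest p. Chromatin modifiers (56 members) had a median of -0.08 that turned to 0.15 with the scanner's log ratio, and an adjusted p of 0.0778; lin-15B, a repressor of germline genes in the soma, was at -0.52 ± 0.11 and mes-6, a subunit of the complex that methylates histone H3, at -0.26 ± 0.08. Nuclear pore and nuclear envelope genes (41 members) had a median of -0.06 that turned to 0.21 with the scanner's log ratio, and an adjusted p of 0.353, with the nuclear pore genes npp-12 at -0.35 ± 0.08 and npp-10 at -0.43 ± 0.12. In each of these 4 lists, 0 members passed adjusted over the list alone. Repair genes passed without array 5 (adjusted p = 0.00444, median 0.17) and with no background correction (0.0341). They also passed with Agilent's processed signals (0.0266), with array weights (0.0133) and with array 3 turned (0.0399). Those weights were 11.6 for array 8 and at most 0.79 for any other array. Without array 6 the repair median turned to -0.03 and that of replication genes to -0.01. Chromatin modifiers passed as lower without array 6 (adjusted p = 0.0307) or array 8 (0.0340), with arrays 6 and 7 averaged (0.0474), with no filter on dim probes (0.0364) or the stricter one (0.0466), and with outlier spots kept (0.0410). With the scanner's log ratio repair and replication genes passed with medians of 0.40 and 0.35 (adjusted p = 1.51e-06 for each) and nuclear pore genes with 0.21 (0.00302), while over the alternatives with the preset correlation the adjusted p of the 4 lists reached 0.943, 0.565, 0.580 and 0.877.

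Oocyte and early embryo lists did not pass either. Genes of egg activation, eggshell and yolk uptake (50 members) had a median of 0.06 that turned to -0.11 with scaling between arrays, and a camera adjusted p of 0.259. The eggshell genes perm-2 and perm-4 were at 0.58 ± 0.14 and 0.54 ± 0.18. In Cy5, 5 of the 50 members were saturated on at least 1 array, which limits the ratios of bright members. Small RNA pathway genes of the germline (46 members) had a median of 0.04 that turned to -0.22 with scaling between arrays, and an adjusted p of 0.729; nrde-2, a nuclear RNAi factor, was at -0.39 ± 0.12. Early zygotic genes (45 members) had a median of -0.04, which was -0.09 without array 5 and -0.03 without array 8, and an adjusted p of 0.208. sdz-30 was at -1.28 ± 0.43 and the homeobox gene ceh-13 at -0.80 ± 0.27. Ubiquitin-like modification genes (28 members) had a median of 0.01 that turned to -0.06 with median centring and -0.17 with scaling between arrays, and an adjusted p of 0.932; ned-8, the ubiquitin-like modifier, was at -0.30 ± 0.08 and uba-1, the ubiquitin-activating enzyme, at -0.29 ± 0.08. In each of these 4 lists, 0 members passed adjusted over the list alone. Eggshell genes passed without array 5 (adjusted p = 0.0326, median 0.17). Without array 6 the medians of eggshell and small RNA genes both turned to -0.07, and that of ubiquitin-like modification to -0.03. Early zygotic genes passed as lower with no background correction (adjusted p = 0.0279, median -0.14), with Agilent's processed signals (0.0266, median -0.25) and with median centring (0.0191, median -0.14). With the scanner's log ratio the 4 lists passed with medians of 0.38, 0.40, -0.36 and 0.32, the largest adjusted p being 0.00157, while over the alternatives with the preset correlation their adjusted p reached 0.926, 0.965, 0.597 and 0.987.

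fem-1 itself was at 0.09 ± 0.09, with a limma adjusted p of 0.559, and its 2 probes went 1 in each direction; hc17 is a temperature-sensitive allele, so that the level of its RNA is no check of the genotype. TGF-beta and insulin pathway components (38 members) had a median of -0.09, which was -0.04 without array 6, and a camera adjusted p of 0.729, with akt-1, a kinase of the insulin pathway, at 0.20 ± 0.07 and let-363, the TOR kinase, at -0.49 ± 0.17, and no member past the threshold. DAF-16 targets, oxidative stress and detoxification genes (52 members) had a median of 0.00 with no settled direction under scaling and an adjusted p of 0.995; adjusted over the list alone 1 member passed, spp-1, and 10 members are also intestine markers. fat-6, a stearoyl-CoA desaturase, was at -0.81 ± 0.15. Apoptosis and corpse engulfment genes (38 members) had a median of -0.04 that turned to 0.11 with the scanner's log ratio and was -0.09 without array 5, and an adjusted p of 0.334, with nuc-1, a nuclease of the lysosome, at -1.94 ± 0.53 and crn-1 at 0.28 ± 0.09. Genes of mitochondrial dynamics, import and quality control (37 members) had a median of 0.08 that turned to -0.22 with scaling between arrays, and an adjusted p of 0.255; pdr-1, the Parkin ligase, was at 0.33 ± 0.10 and tomm-40, the import channel, at 0.50 ± 0.15. In the lists of TGF-beta and insulin, apoptosis and mitochondrial dynamics, 0 members passed adjusted over the list alone. Without array 6 the median of mitochondrial dynamics genes turned to -0.03. These genes passed with the scanner's log ratio (median 0.38, adjusted p = 0.000633, against 0.880 with scaling between arrays).

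Markers of other cells differed between the arrays. Sperm and spermatogenesis markers, which a feminised germline should lack, had a median of 0.23, with 84 of 96 members above 0 (camera adjusted p = 8.63e-08, and 0.610 with an estimated correlation). The list median was above 0 on 5 of 5 arrays, but only at 0.01 on array 5. The list was dim, with a median log2 signal of 7.40, against 11.05 for maternal RNA regulators. ssq-1, a sperm protein gene, was at 0.81 ± 0.20 and gsp-3 at 0.51 ± 0.15; adjusted over the list alone, 0 members passed. The 25 major sperm protein genes, near-identical copies that share probe signal, had a median of 3.51 on array 3, and of 0.04, -0.06, 0.54 and 0.68 on arrays 5, 6, 7 and 8. The other 71 sperm markers had medians between 0.00 and 0.19 on the 5 arrays. The list call was lost with the sign of array 3 turned (adjusted p = 0.585, the highest with the preset correlation, from 1.65e-13), and the median turned to -0.06 there. The list median was 0.15 without array 3, without array 6 and with scaling between arrays, and 0.65 with Agilent's processed signals.

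Hypodermis and cuticle markers (206 members) had a median of 0.06 and a camera adjusted p of 0.283, with col-113, a collagen, at 0.42 ± 0.10 and dpy-14, a cuticle collagen, at -2.05 ± 0.59. Their median was 0.62 on array 3 and between -0.17 and -0.01 on the other arrays; without array 3 it was -0.17 and the list passed as lower (adjusted p = 0.00129), and it was also below 0 under every scaling alternative but scaling between arrays. The list passed as higher without array 6 (0.0272), 7 (0.0252) or 8 (0.00586), and its adjusted p reached 0.895 without array 5. The 124 cuticle collagen genes of the col class had a median of 1.48 on array 3, with 73 of them over 2-fold higher at day 8, and of -0.29 on array 8, with 33 over 2-fold lower. Body wall muscle and pharynx markers (41 members) had a median of 0.07 and an adjusted p of 0.283, with unc-15, paramyosin, at 0.53 ± 0.19 and a median of 0.30 on array 3; without array 3 the list median turned to -0.04, and the list passed without array 8 (0.0340) and had an adjusted p of up to 0.947 over the alternatives with the preset correlation. Neuron markers (57 members) had a median of -0.02 that turned to 0.00 with scaling between arrays, and to 0.01 without array 6 or array 7, and an adjusted p of 0.784, with mec-7, a tubulin, at -0.20 ± 0.08. Gonadal sheath, spermatheca and uterus markers (37 members) had a median of 0.09, which was 0.02 without array 6 and 0.14 without array 5, and an adjusted p of 0.119, with inx-9, a gap junction protein of the sheath, at 0.89 ± 0.27. Coelomocyte markers (11 members) had a median of 0.05 that turned to -0.01 with median centring and to 0.00 with scaling between arrays, and an adjusted p of 0.774, with lmp-1, a lysosomal membrane protein, at -1.18 ± 0.35. In each of these 5 lists, 0 members passed adjusted over the list alone.

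**Figure D4:**
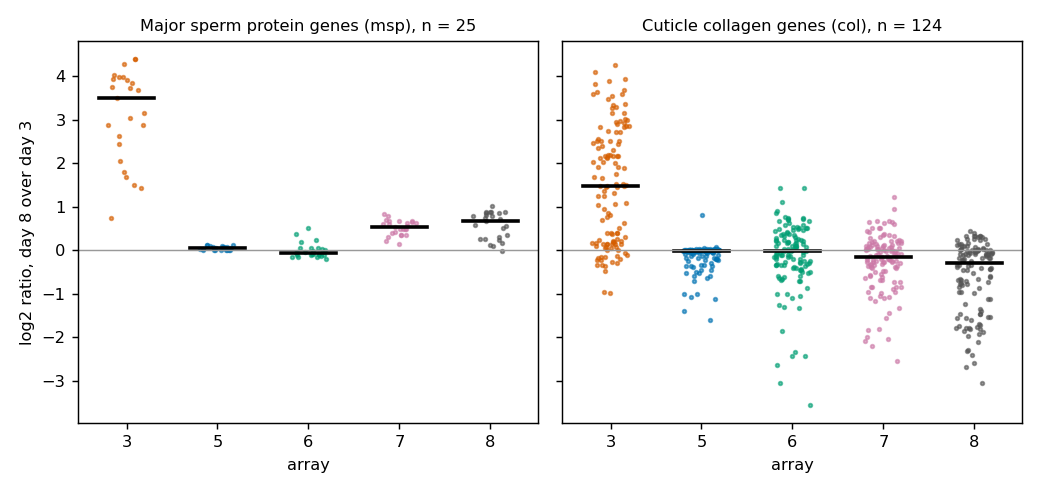
Day 8 over day 3 log2 ratio of the 25 major sperm protein genes (left) and the 124 cuticle collagen genes (right) on each array; points are genes, spread sideways for display, and black bars are medians. The medians on array 3 are 3.51 and 1.48; on the other 4 arrays they lie between -0.06 and 0.68 for the sperm genes and between -0.29 and -0.01 for the collagen genes.

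Among 150 gene classes named by the letters before the hyphen, 14 passed the preset camera test and 0 passed with an estimated correlation (adjusted p = 0.824 with an estimated correlation for each) or by fry for change in 1 direction. Classes of paralogs can share probe signal. The smallest p was that of fbxb, a class of F-box genes: its 93 genes had a median of -0.69, with 91 below 0 (camera adjusted p = 8.02e-15), and the 38 F-box genes of fbxc a median of -0.45 (5.74e-05). The F-box class with the most genes tested, fbxa, did not pass, with 70 genes below and 56 above 0 (adjusted p = 0.535). With the scanner's log ratio the medians of fbxb and fbxc were -1.73 and -1.42, and with Agilent's processed signals that of fbxb was -1.60. Nuclear hormone receptors (nhr, 201 genes) had a median of -0.19 (0.000126), SKP1-related ubiquitin ligase components (skr, 18 genes) -1.13 (0.0148), and the zygotically expressed class sdz (30 genes) -0.42 (0.00185). With the scanner's log ratio nhr and sdz were at -0.55 and -1.11, and with scaling between arrays nhr and skr were at -0.09 and -0.61. The mitochondrial ribosomal class mrps (27 genes) had a median of 0.13 that turned to -0.14 with scaling between arrays (0.0267). On array 5 the medians of fbxb, fbxc, nhr, skr and sdz lay between -0.08 and 0.00, and on array 6 between -2.74 and -0.37. The remaining classes were his, rpl, msp, rps, lido, srz, atg and srg. The medians of srz and srg, both higher, were 0.08 each (camera adjusted p = 0.0296 and 0.0393).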

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

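All tests of explanations in this part but those of a noisy hybridisation and of other-cell RNA on array 3 were chosen after the result was seen, including the use of the 10 splits of the same sizes.

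A sample far from the other 4 arrays was looked for in 12 quality measures, 34 list medians and 145 named genes, by the gap to the nearest array over the whole range (above 0.71). This marked 5, 4 and 9 of them, where chance would mark 0.6, 1.7 and 7.2. Array 6 stood apart in the share of day 3 probes above background (83.8%, gap 0.758), in saturated Cy5 spots (0.121%, gap 0.847), in saturated Cy3 spots (0.109%, gap 0.894) and in genes over 2-fold higher at day 8 (8.25%, gap 0.743). Array 3 had the highest Cy5 background (34.5, gap 0.75). Array 6 also had the highest list medians of DNA replication (0.26, gap 0.809), maternal RNA regulators (1.12, gap 0.799) and eggshell genes (0.50, gap 0.731), and array 3 that of cuticle markers (0.62, gap 0.791).

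Among genes, array 6 was the highest for inx-14 (1.66, gap 0.807), psf-2 (1.21, gap 0.816), spe-39 (gap 0.878) and osm-11 (2.29, gap 0.755), and the lowest for hsp-4 (-0.52, gap 0.771) and ned-8 (-0.54, gap 0.715). Array 5 was the lowest for fat-2 (-1.67, gap 0.725). Array 3 was the highest for cup-2 (0.16, gap 0.712) and msp-113 (4.40, gap 0.796).

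Array 3 did not share the change of the other arrays, with a mean r of -0.0395 against a lowest r of 0.224 among the others. With its sign turned, its highest r was 0.130, still below that value, which argues against dyes labelled the wrong way round. Replicate spots on it correlated at 0.957, above the lowest other array (0.934). That lowest value was on array 5, which had the narrowest ratios, and such a correlation also depends on the spread of the ratios. The SD between replicate spots was 0.083 on array 3, and from 0.051 (array 5) to 0.095 (array 6) on the others. These values argue against noisier spots on array 3. Noise from the RNA or its labelling is shared by replicate spots, so that they cannot speak to it. RNA of other cells stays open: without 480 marker genes of such cells its mean r was -0.0137, but most genes that such RNA would move are not among the markers, so that this value excludes nothing. Its separate slide and scan cannot be told apart from its samples, since 1 array lay on that slide and scan, and a difference between its collections stays open as untested, including whether its day 8 sample held oocytes alone: major sperm protein genes had a median of 3.51 and cuticle collagen genes of 1.48 on it.

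Ribosomal protein genes were higher at day 8 in the fit, with a median of 0.21 with the dye term and of 0.11 without it. An equal dye effect on all arrays is therefore not what raised the fitted median, but the list call did not hold (adjusted p = 0.610 with an estimated correlation), and a dye effect that differs between arrays may still be part of it. The 12 members never saturated had a median of 0.32 and a dye term of -0.13 and passed (camera adjusted p = 0.00921; adjusted p = 0.704 with an estimated correlation), but their array medians were 0.84 and 0.57 on arrays 6 and 7, of shared collection days, and -0.02, -0.08 and 0.06 on arrays 3, 5 and 8. Saturation of their own spots is excluded for these 12 members, whether or not their shift holds. An effect through the loess, in which saturated spots kept their weight, is not excluded. Saturation stays open for the 51 members saturated on some array, whose red over green was lower than that of the others on 4 of 5 arrays. The age of the oocytes stays open as well.

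Intestine markers were lower at day 8 by the preset test (adjusted p = 0.610 with an estimated correlation, and 0.0894 with the preset one without array 5), and a candidate explanation is 1 lower share of gut RNA at day 8. With arrays 6 and 7 averaged, 2 of 47 members, act-5 and ctl-2, were higher by over 0.5 log2 in at least 2 of the 4 collections. This was 4.26%, against 1.24% of other genes (two-sided Fisher's exact p = 0.117). The limit of at most 2 members under this explanation was set after the values were seen, so that the count decides nothing. On arrays 5 and 8, 44 and 42 members were lower, and on arrays 3, 6 and 7 between 25 and 28, with 8 members on each of these 3 arrays higher by over 0.5 log2. The 3 brightest members, far-2, asp-1 and asp-5, were at 0.17, -0.25 and 0.12. A lower share of gut RNA and a change with age both stay open.

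Splits of the 5 arrays into groups of 3 and 2 number 10, the real one included, too few for a share under 0.05. The real split called 0 genes, 12 lists and 14 classes; the highest of the other splits called 0, 14 and 22. With the real split counted, all 10 had as many genes, 5 as many lists and 6 as many classes. At an unadjusted p under 0.05 the real split had 1129 genes, the highest of the others had 1236, and 3 of the 10 had at least as many as the real one, itself included. A split compares red over green between its groups. Arrays 6 and 7, with shared collection days, carry opposite dyes, so that a change they share cancels when they are set against the others. That split called 0 genes, 9 lists and 7 classes, and cannot speak to an effect of the collection days. With arrays 6 and 7 averaged, the real comparison called 0, 13 and 14. A further 5 splits set 1 array alone. Their counts are not given, since a lone array has no spread of its own, and whether a structure of the samples lies behind them was not tested.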

How the results depend on the processing

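The alternatives that scale between arrays, leave out arrays 6 and 7 or array 3 with no dye term, turn array 3 or leave out saturated genes were chosen after the data were seen. In every gene-level alternative run, 0 genes were called at an adjusted p under 0.05, and 0 at 0.10 or with a 2-fold limit in the fit as reported; the smallest adjusted p was 0.0911, without array 5, and genes at an unadjusted p under 0.05 numbered from 211, with arrays 6 and 7 averaged, to 5973, without array 5. The count was 1932 with no dye term, 2028 with scaling between arrays, 2615 with no background correction, 3374 with Agilent's processed signals, 3411 with the scanner's log ratio or the deposited series values, and 3441 with slide as a random block, whose estimated correlation was -0.0998. Lists shifted numbered 22 and classes 34 with the scanner's log ratio and with the series values, which are the same ratios, and 0 and 0 with an estimated correlation and with fry, for the lists and classes alike. Without array 3 and no dye term, 22 classes shifted. Leaving out each array gave 11 to 16 lists and 12 to 17 classes. Against the reported direction, with the scanner's log ratio and with the series values alike the medians were 0.30 for kinetochore, 0.20 for spindle, 0.073 for heat shock, 0.18 for RNA splicing and 0.21 for nuclear pore, and the median for ubiquitin-like modification, whose test had pointed lower, was 0.32. Cuticle markers were at -0.17 without replicate 3, at -0.17 without array 3 and no dye term and at -0.33 with array 3 turned. Sperm markers were at -0.06 with array 3 turned. The cause of these changes was not tested, apart from the array left out or turned in the settings that name it. Aquantile left the log ratios as they were and tests nothing. Collection day as a random block was not run, since limma estimates no correlation for 4 days over 5 arrays. No paired analysis was possible because the ratios within each array, which the fit uses, already pair the ages and leave no further pairs to block. Signal over background limits dim genes, most on array 5, where the median Cy3 signal was 50.5 over a background of 23.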

Other observations

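No explanation is offered in this part, and its values were chosen after they were seen. Cuticle genes other than the collagens of the col class were also far from 0 on single arrays. rol-1, a cuticle gene, was at 4.24 on array 3 and at -2.38 on array 8, with a fitted value of -0.02 ± 1.05. dpy-13, a cuticle collagen, was at 3.78 on array 3 and at -2.83 on array 8, with a fitted value of 0.08 ± 1.01. Neither passed the test.

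F-box genes of the fbxb class had medians of -1.43, -1.35 and -0.67 on arrays 6, 7 and 8, and of -0.02 and -0.08 on arrays 3 and 5. SKP1-related genes of the skr class had medians of -2.74, -1.82 and -0.44 on arrays 6, 7 and 8, and of 0.16 and -0.08 on arrays 3 and 5. Both kinds of protein belong to the same family of ubiquitin ligases. cav-1, caveolin of the oocyte, was at -4.53 and -2.85 on arrays 6 and 7, at -1.50 on array 5, also below 0 on array 8, and at 0.88 on array 3, with a fitted value of -2.02 ± 0.73 and a limma adjusted p of 0.374.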
